A study of Homo sapiens with 6 samples.

How the data were processed

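The series holds RNA sequencing of FaDu, an established cell line of hypopharyngeal squamous carcinoma. The labels put 3 libraries in a group carrying a short hairpin RNA against NSUN2 (shNSUN2) and 3 libraries in a group without a hairpin (FaDu). No library with a non-targeting hairpin was used here, so effects of NSUN2 loss, of the hairpin and of its delivery and selection share 1 comparison. The series' design text speaks of 3 pairs of repeated experiments without saying what a pair shares. Nothing in the labels says whether the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The extraction notes give total RNA with an integrity check before library preparation, and no source used here says whether RNA was selected by its poly(A) tail or whether strand was kept.

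The values are estimated counts per gene as deposited by the authors, 1 table of 58825 Ensembl gene identifiers and 6 columns. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2, without saying which made the table. The same notes give the mouse build mm8, which cannot have given human identifiers. The human build and annotation behind the counts are not given in the sources used here. The values are whole numbers and were used as they stand. The value 4 occurred 3.25 to 3.81 times as often as the mean of the values 3 and 5, so 1 sequenced fragment is often worth 4 units, and low values carry more counting error than their size shows. For that reason no Poisson or binomial interval is given. No row named anything but a gene, and every column matched a sample by its title.

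Symbols were taken from a gene name table (58472 identifiers matched) and from GENCODE 29 on GRCh38 (58552 matched), which left 58817 identifiers with a symbol. Positions are those of GENCODE 29. Without strand information, overlapping and antisense genes cannot be told apart, and genes with close copies (the ribosomal proteins and FTH1 with their pseudogenes, CEACAM5 with CEACAM6, KLK2 with KLK3, the histone genes) have uncertain counts.

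Totals were 61196901, 53612358 and 72043755 units in the FaDu libraries and 67421386, 58577723 and 72788971 in the shNSUN2 libraries. Genes were tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest with robust estimation, TMM scaling and filterByExpr by group (minimum count 10, minimum total 15), which kept 19081 genes. The design held the group alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are the counts scaled by edgeR to the TMM-adjusted library total, given as mean ± SD over 3 libraries, except in the share of smooth muscle and plasma cell genes in the closing section, which used plain library totals. NSUN2 was also compared by an exact two-sided permutation test of its CPM, whose smallest possible p with 10 splits is 0.1.

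Before the data were examined, 42 gene lists were fixed, and 41 had at least 5 tested genes. The list of leukocyte markers had 3 of its 17 genes tested and was not run. Lists were tested with limma 3.58.1, by camera on voom values with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 41 lists, and again with an estimated correlation, with fry and with ranks. The genes named in the text were also set by a rule fixed beforehand. It takes NSUN2, any tested member of the lists of RNA m5C factors and Hippo pathway components, the 12 higher and the 12 lower genes with the largest log2 fold change among called genes with at least 5 CPM in the higher group and no overlap between groups, and the 4 members with the smallest adjusted p of each list that was called or had at least 3 members called. Genes with near-identical copies were to be passed over. That exclusion was given its concrete form (protocadherin clusters, 7SK RNA, read-through genes) once the ranking had been seen, and it removed ENSG00000283765, STX16-NPEPL1, PCDHGB7 and RN7SK. The 4 long noncoding RNAs described as resembling ribosomal DNA were picked after they had been seen among the genes that fell. Before the final tests, single genes, gene name families and windows along the chromosomes were also looked over. The windows are not reported, and what is named from the rest is marked as chosen after its values were seen. Single values of a few genes that these rules would name are not reported here, and those genes stay in the counts of their lists.

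The procedure was tested on simulated data with 10 draws of 18463 genes, at the means, spread and totals of these libraries. Counts were drawn in single units, without the steps seen in the deposited values. Recovery and false calls may therefore differ for genes of low counts. Among 50 genes per size, edgeR recovered 1.6% of changes of 0.5 on the log2 scale, 34.1% of changes of 1, 78.7% of changes of 2 and 86.9% of changes of 3. No other genes were changed, a far smaller share than the 3532 called of 19081 tested in the data. The cutoff of an adjusted p depends on that share, so recovery and false calls may differ in the real comparison. False calls made up 8.86% of calls on average (6.48% to 13.3% between draws), above the nominal 5%. A first version with a single draw had the highest of these shares and exceeded a bound of 10% set for it, after which the 10 draws were made. With no change simulated, 1 gene was called. With every member of 1 list shifted by 0.5 in 1 draw, camera called that list and no other. Genes were drawn independently there, so this cannot check list calls at the preset correlation where genes are correlated.

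The alternatives planned beforehand were the size factors of DESeq2 in edgeR, scaling by totals alone, no filter, a filter of 1 CPM in 3 samples, the Wald test of DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each library in turn, and an adjusted p under 0.01. After the data had been seen, 3 were added. They removed a loess trend of each library on GC content and exonic length (values for 99.75% of the tested genes), left out mitochondrial and ribosomal DNA-like transcripts, or divided the counts by 4. In the comparison of settings, a change of sign counted as a reversal only where the value was called in at least 1 of both fits. The label of replicate numbers does not say what a pair of experiments shares.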

Results

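Gene expression was measured by RNA sequencing in FaDu cells, a line from a squamous carcinoma of the hypopharynx, with and without a short hairpin RNA against NSUN2. NSUN2 is a methyltransferase that places 5-methylcytosine (m5C) on tRNAs and some mRNAs. There were 3 libraries per group, with totals of 53612358 to 72788971 estimated counts. Pearson's r of log2 CPM across genes was 0.964 to 0.974 within groups and 0.935 to 0.953 between groups. The first principal component held 47.7% of the variance and separated the groups. Replicate 3 of shNSUN2 stood apart from its group by the GC content and length of its genes. Its log2 difference from replicate 1 correlated with GC content at a Spearman rho of 0.602 across 11538 genes and with exonic length at -0.413, and its difference from replicate 2 at 0.52 and -0.366. Genes are not independent replicates.

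The series asks which transcripts change when NSUN2 is knocked down. NSUN2 itself lies on chromosome 5 from 6599239 to 6633291 (GRCh38). It had 169, 173 and 156 CPM in the FaDu libraries and 50.4, 34.7 and 39.6 CPM in the shNSUN2 libraries. Its mean fell from 166 ± 8.94 to 41.6 ± 8.05 CPM (SD, n = 3), which is 25.1% of the FaDu level. The log2 fold change was -1.997 (SE 0.16, edgeR adjusted p = 0.000526). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

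**Figure D1:**
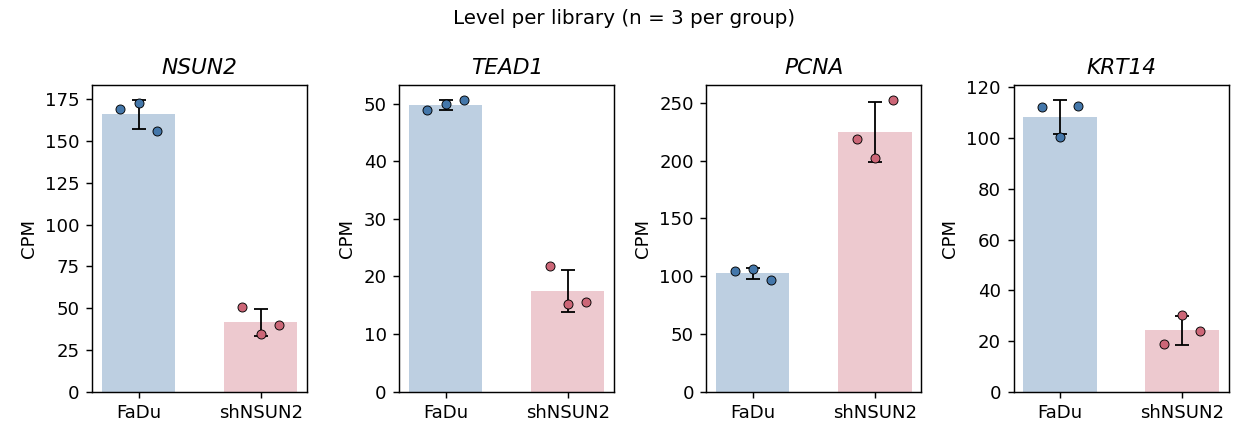
Level of NSUN2, TEAD1, PCNA and KRT14 in CPM (vertical axis from 0) in the FaDu and shNSUN2 groups; points are the 3 libraries of a group, bars their mean and error bars the SD. In each of the 4 genes all shNSUN2 libraries lie outside the range of the FaDu libraries, with NSUN2, TEAD1 and KRT14 lower and PCNA higher.

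At a preset correlation between genes, lists of G1/S phase and keratinocyte differentiation genes were called higher in shNSUN2, and lists of basal keratinocyte, basement membrane and ATF4 stress genes lower. With an estimated correlation none of them was called. Of 19081 genes tested, 3532 were called, 1629 higher and 1903 lower in shNSUN2. At least 2-fold changes were more often decreases, with 441 genes higher and 1118 lower. The number of calls depended on single libraries, and was 1596, 1356 and 1354 without FaDu replicate 1, 2 or 3 and 2069 without shNSUN2 replicate 1. With a GC and length correction chosen after the data had been seen, 2729 genes were higher and 2217 lower in shNSUN2, so the balance turned towards increases.

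The largest increases were in genes nearly silent in the parental cells. CEACAM6, a cell adhesion glycoprotein of epithelia, went from 0.0668 ± 0.116 to 70.6 ± 7.56 CPM, and its neighbour CEACAM5 from 0.0178 ± 0.0309 to 6.72 ± 1.92 CPM (edgeR adjusted p = 0.000849 and 0.000596). The kallikreins KLK3 and KLK2, secreted proteases best known from the prostate, reached 13.7 ± 3.30 and 9.91 ± 1.68 CPM from 0.0534 ± 0.0926 and 0.0641 ± 0.01 CPM. The FaDu levels of these 4 genes rest on few counts, so no fold is given. In the same shNSUN2 libraries other prostate transcripts were detected that were listed at 0 in every FaDu library, such as MSMB at 3.92, 0.488 and 0.281 CPM (chosen after its values were seen). PI3, an epidermal protease inhibitor, rose by a log2 fold of 4.97 (SE 0.22) and KRT13, a keratin of mucosal squamous epithelium, by 4.04 (SE 0.26). CDH5, the cadherin of endothelial junctions, rose from 1.39 ± 0.460 to 39.6 ± 11.3 CPM. CP, VGLL1, RELN, SPNS2 and S100A9 rose by log2 folds of 4.82, 4.14, 3.99, 3.74 and 3.62. The FaDu means of CP, PI3, VGLL1 and SPNS2 were 0.282, 0.514, 0.772 and 0.998 CPM. Their folds therefore also rest on few counts and are uncertain. VGLL1 encodes a cofactor of TEAD transcription factors.

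Among the 12 largest decreases, SERPINB13, a serpin of squamous epithelium, fell from 82.1 ± 3.41 to 4.98 ± 1.70 CPM (log2 fold change -4.05, SE 0.26, edgeR adjusted p = 0.000316). The basement membrane protein NID1 fell from 51.0 ± 12.6 to 4.40 ± 0.553 CPM and the cyclin CCNA1 from 28.98 ± 0.998 to 1.83 ± 0.552 CPM. INHBE and ALDH1L2, both known targets of the stress factor ATF4, fell by 3.89 and 3.46 on the log2 scale. FLI1, MSC, GPR176, NEURL1, FHL1, MMP28 and PTPRZ1 fell by 3.59 to 4.04. All of these but FHL1 had shNSUN2 means of 0.344 to 0.638 CPM, so their folds rest on few counts.

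Of the 41 gene lists tested, camera called 19, with 12 higher and 7 lower in shNSUN2, at a preset correlation between genes of 0.01. With an estimated correlation no list was called, and that adjusted p is given beside each list. These calls therefore rest on the preset correlation. The called members of the 19 lists, 155 higher and 79 lower, were fewer without FaDu replicate 1, 2 or 3 (78, 63 and 61 higher and 50, 46 and 51 lower) and without shNSUN2 replicate 1 (105 and 55). Single lists lost more than these sums show. More members were called without shNSUN2 replicate 3 (199 and 90) and with the GC and length correction (236 and 92). Of the 19 lists, fry called 13.

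Both cell cycle lists were higher. Of 44 genes of the G1/S phase, 31 rose and none fell (37 adjusted over the list alone), with a median log2 fold of 0.74 (camera adjusted p = 2.11e-18, adjusted p = 0.177 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, rose from 103 ± 4.91 to 225 ± 26.0 CPM, and RRM2, a subunit of ribonucleotide reductase, by 1.33 (SE 0.15) on the log2 scale. The replicative helicase subunits MCM4 and MCM6 rose by 1.15 and 0.89. Of 52 G2/M genes, 15 rose and none fell, with a median log2 fold of 0.32 (19 adjusted over the list alone; camera adjusted p = 6.94e-07, adjusted p = 0.177 with an estimated correlation), among them the tubulin TUBB4B by 1.20 (SE 0.19). The counts depended on single libraries. Without FaDu replicate 1, 2 or 3 or shNSUN2 replicate 1, the G1/S genes that rose numbered 23, 20, 18 and 24 and the G2/M genes 3, 1, 2 and 8, while without shNSUN2 replicate 3 they were 39 and 38. The medians moved less than the counts. Without FaDu replicate 1, 2 or 3 or shNSUN2 replicate 1, the G1/S median was 0.78, 0.78, 0.71 and 0.68. The G2/M median was 0.30, 0.36, 0.33 and 0.27 in the same order. Housekeeping reference genes had a median log2 fold of 0.291 in the main fit, so a rise of the G2/M size was not particular to the cell cycle.

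Lists of ribosome and mitochondrial protein genes were also higher. Of 30 ribosome biogenesis and MYC-associated genes, 14 rose and none fell (25 adjusted over the list alone), with a median log2 fold of 0.61 (camera adjusted p = 2.87e-09, adjusted p = 0.452 with an estimated correlation). They include SLC19A1, a folate carrier, and the nucleolar NOLC1, which rose by 1.08 and 0.69. Of 72 mitochondrial ribosomal proteins 15 rose (21 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.81e-08, adjusted p = 0.537 with an estimated correlation, fry adjusted p = 0.0856), and of 63 nuclear subunits of oxidative phosphorylation 13 rose (14 adjusted over the list alone; camera adjusted p = 1.43e-06, adjusted p = 0.555 with an estimated correlation, fry adjusted p = 0.125). MRPL27 rose by 0.92, and NDUFC2 and ATP5MC3 by 0.89 and 0.97. Of 75 cytosolic ribosomal proteins 6 rose (1 adjusted over the list alone; camera adjusted p = 0.00141, adjusted p = 0.617 with an estimated correlation, fry adjusted p = 0.319), with RPS26 at a log2 fold of 1.38 (SE 0.19). That list was no longer called without shNSUN2 replicate 3, where its median log2 fold was 0.03 and its camera adjusted p = 0.387. Of 35 tRNA modification enzymes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.00222, adjusted p = 0.453 with an estimated correlation, fry adjusted p = 0.0537), with ADAT3, a subunit of a tRNA adenosine deaminase, at 2.28 (SE 0.32). ADAT3 had a FaDu mean of 0.53 CPM, so its fold rests on few counts. Of 17 heat shock genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.0293, adjusted p = 0.54 with an estimated correlation, fry adjusted p = 0.101), a list no longer called without shNSUN2 replicate 1 or 3 (camera adjusted p = 0.0683 and 0.0784). Of 25 housekeeping genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000452, adjusted p = 0.477 with an estimated correlation, fry adjusted p = 0.0516), and the proteasome subunit PSMB2 rose by 1.02. This list of reference genes had a median log2 fold of 0.291. The medians were 0.324 for the G2/M genes above, 0.32 for oxidative phosphorylation and 0.282 for heat shock genes. They were 0.195 for tRNA modification enzymes and 0.185 for cytosolic ribosomal proteins. Rises of this size were therefore not particular to the pathway lists. Without FaDu replicate 1, 2 or 3 or shNSUN2 replicate 1, the genes that rose numbered 4, 4, 2 and 6 for ribosome biogenesis and MYC-associated genes, 6, 2, 1 and 7 for mitochondrial ribosomal proteins and 3, 4, 3 and 10 for oxidative phosphorylation. Median log2 folds moved less, at 0.613, 0.639, 0.575 and 0.582 for ribosome biogenesis genes. They were 0.427, 0.359, 0.37 and 0.465 for mitochondrial ribosomal proteins and 0.308, 0.306, 0.272 and 0.392 for oxidative phosphorylation. In the same fits the cytosolic ribosomal proteins that rose numbered 1, 1, 1 and 5, the tRNA modification enzymes 2, 1, 1 and 3, the heat shock genes 0, 0, 0 and 1, and the housekeeping genes 3, 3, 2 and 6. Without shNSUN2 replicate 2 or 3, 5 heat shock genes rose. No housekeeping gene fell when any library but shNSUN2 replicate 3 was left out.

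**Figure D2:**
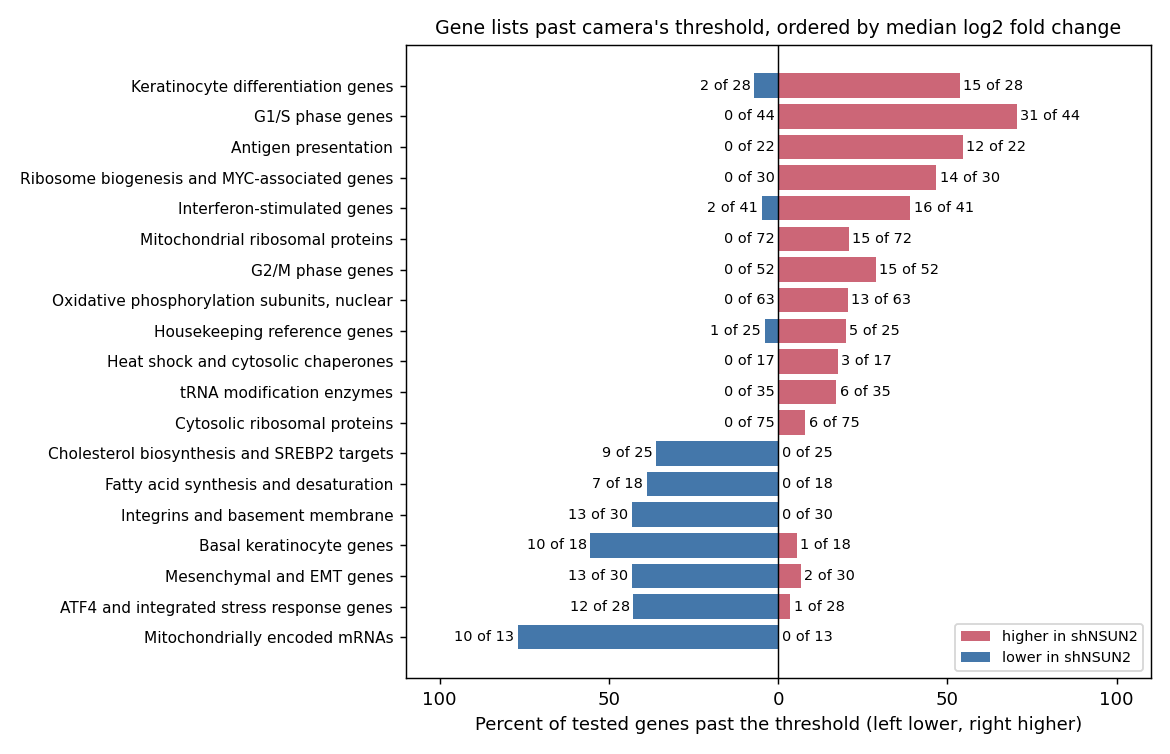
The 19 gene lists past camera's threshold at the preset correlation, ordered by median log2 fold change; the horizontal axis gives the percent of a list's tested genes called lower (left, blue) or higher (right, red) in shNSUN2, with the counts beside the bars. The G1/S list has 31 of 44 genes higher and the mitochondrially encoded mRNAs 10 of 13 lower.

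Most mRNAs of the mitochondrial genome fell, whereas none of the 63 nuclear subunits of oxidative phosphorylation did (1 without shNSUN2 replicate 3). The 13 mRNAs made up 7.96% ± 0.821 of counts in FaDu and 3.97% ± 0.395 in shNSUN2 (SD, n = 3). Of the 13, 10 fell (10 adjusted over the list alone), with a median log2 fold of -0.77 (camera adjusted p = 6.94e-07, adjusted p = 0.452 with an estimated correlation). MT-ND4 and MT-ND4L, which share 1 mRNA, had log2 folds of -1.69 (SE 0.14) and -1.501 (SE 0.12), and MT-CO3 and MT-CO1 fell by 1.35 and 1.01. MT-ATP8 and MT-ATP6 also share 1 mRNA but were apart, at -1.08 (SE 0.165) and -0.32 (SE 0.46), and MT-ATP6 had 2720 CPM in shNSUN2 replicate 2 against 938 and 879 in replicates 1 and 3. MT-ND1 at 0.15 (SE 0.12), MT-ND2 at -0.20 (SE 0.14) and MT-ATP6 did not pass the test. Of the rRNAs, looked at after their values were seen, the 12S MT-RNR1 rose by 0.97 (SE 0.14) and the 16S MT-RNR2 was at 0.09 (SE 0.17), not past the test. The 4 noncoding RNAs that resemble ribosomal DNA also differed, with 0.563% ± 0.397 of counts in FaDu (0.336% without FaDu replicate 1) and 0.059% ± 0.012 in shNSUN2.

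**Figure D3:**
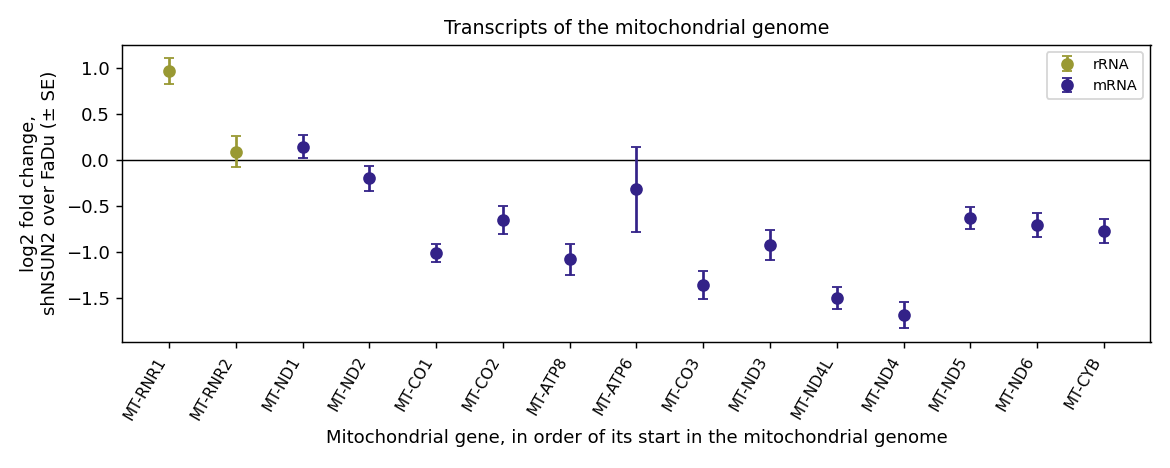
Log2 fold change of shNSUN2 over FaDu for the 13 mRNAs (blue) and 2 rRNAs (olive) of the mitochondrial genome, in the order of their start positions; points are edgeR estimates from 3 libraries per group and error bars the SE. The values run from 0.97 for MT-RNR1 to -1.69 for MT-ND4.

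Differentiation and basal genes of keratinocytes moved in opposite directions. Of 28 differentiation genes 15 rose and 2 fell (16 and 3 adjusted over the list alone), with a median log2 fold of 1.65 (camera adjusted p = 2.44e-06, adjusted p = 0.177 with an estimated correlation). The median stayed the same with the 2 genes at 0 in FaDu set to a floor of 3 counts per library. As 2 of 28 genes can hardly move a median, this says little of how firm it is. LCN2, a secreted siderophore-binding protein, rose from 47.5 ± 6.36 to 164 ± 15.3 CPM. Of 18 basal keratinocyte genes 10 fell and 1 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.000366, adjusted p = 0.177 with an estimated correlation). The basal keratins KRT14, KRT5 and KRT17 fell by 2.16, 1.12 and 0.99 on the log2 scale, whereas KRT15 rose by 2.67 (SE 0.18). Without FaDu replicate 1, 2 or 3 the basal genes that fell numbered 5, 6 and 5, and 2 rose without shNSUN2 replicate 3.

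Lists of integrin and basement membrane genes and of mesenchymal genes were lower. Of 30 integrin and basement membrane genes 13 fell and none rose (17 adjusted over the list alone; camera adjusted p = 1.83e-06, adjusted p = 0.177 with an estimated correlation). Without FaDu replicate 1, 2 or 3 or shNSUN2 replicate 1 the 13 were 6, 6, 6 and 7. Besides NID1, the collagen COL4A2 fell by 2.16 and the laminins LAMB1 and LAMB2 by 1.26 and 1.11. Of 30 mesenchymal genes 13 fell and 2 rose (14 and 3 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.265 with an estimated correlation), with COL6A2, LOX and PDPN at log2 folds of -3.10, -2.89 and -1.86. COL6A2 and LOX had shNSUN2 means of 0.75 and 0.92 CPM, so their folds rest on few counts. Without FaDu replicate 1, 2 or 3, 1 mesenchymal gene rose each time, and without shNSUN2 replicate 1 none did.

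Lists of ATF4 stress, fatty acid synthesis and cholesterol synthesis genes were lower, though most of their members did not pass the test. Of 28 ATF4 and integrated stress response genes, 12 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 2.29e-05, adjusted p = 0.453 with an estimated correlation). SLC7A5 and SLC3A2, the subunits of a large amino acid transporter, fell from 2399 ± 127 to 1168 ± 82.5 CPM and from 646 ± 43.1 to 346 ± 33.5 CPM, and PHGDH, the first enzyme of serine synthesis, fell by 1.31. No gene of this list rose without FaDu replicate 2 or shNSUN2 replicate 2. Of 18 fatty acid synthesis genes 7 fell (10 adjusted over the list alone; camera adjusted p = 0.000367, adjusted p = 0.177 with an estimated correlation), with SCD, the stearoyl-CoA desaturase, lower by a log2 fold of -1.43 and ACSS2 by -1.42. Of 25 cholesterol synthesis genes 9 fell and none rose (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.453 with an estimated correlation), among them MSMO1 at -1.21 (SE 0.14) and the squalene epoxidase SQLE at -0.81 (SE 0.12). The 9 were 3, 3 and 4 without FaDu replicate 1, 2 or 3 and 5 without shNSUN2 replicate 1.

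Lists of interferon-stimulated and antigen presentation genes were higher. Of 41 interferon-stimulated genes 16 rose and 2 fell (19 and 3 adjusted over the list alone; camera adjusted p = 0.000366, adjusted p = 0.452 with an estimated correlation). Without FaDu replicate 2 the 16 were 9. None fell without FaDu replicate 1 or 2 or shNSUN2 replicate 1, 1 fell without FaDu replicate 3 and 4 without shNSUN2 replicate 3. MX1 rose from 15.2 ± 1.84 to 61.3 ± 19.6 CPM and OAS3 from 290 ± 15.8 to 655 ± 116 CPM. XAF1 was listed at 0 in every FaDu library and had 1.36 ± 0.773 CPM in shNSUN2. Of 22 antigen presentation genes 12 rose and none fell (15 adjusted over the list alone; camera adjusted p = 2.33e-06, adjusted p = 0.452 with an estimated correlation). The 12 were 6, 4 and 4 without FaDu replicate 1, 2 or 3 and 8 without shNSUN2 replicate 1. The immunoproteasome subunits PSMB8 and PSMB10 rose by 1.12 and 1.25. CD74, the chain that accompanies HLA class II, rose from 0.365 ± 0.0337 to 2.40 ± 1.05 CPM in libraries that also held immunoglobulin transcripts, such as IGKC at 2.87, 0.505 and 0.844 CPM against 0 in FaDu (chosen after its values were seen).

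Of the 5 lists chosen from the study's subject, camera called the tRNA modification enzymes above and not the other 4. Of 18 Hippo pathway components 4 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.361, fry adjusted p = 0.0141 for lower). TEAD1, a transcription factor of this pathway on chromosome 11 from 12674591 to 12944483, fell from 49.8 ± 0.901 to 17.5 ± 3.68 CPM (log2 fold change -1.51, SE 0.17, edgeR adjusted p = 0.0016). This list was chosen from what is known of NSUN2 and TEAD1 in this cell line, which may rest on these libraries, so TEAD1 is not independent evidence. TEAD2, TEAD3 and TEAD4 were at 0.16, 0.05 and 0.26 and did not pass the test, and the coactivators YAP1 and WWTR1 were at -0.28 (SE 0.12) and -0.03 (SE 0.11). PTPN14 and the kinase STK4 fell by 1.13 and 0.98, and AMOT rose by 1.45. VGLL4 at -0.73 and NF2 at 0.51 lost their calls when any 1 FaDu library was left out (adjusted p = 0.0504 to 0.0538 and 0.0857 to 0.163), and NF2 also without shNSUN2 replicate 1 or with no filter (adjusted p = 0.106 and 0.0546). Of 22 targets of YAP, TAZ and TEAD, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.89), with IGFBP3 at 2.42 (SE 0.16), TGFB2 at 3.62 (SE 0.39) and the receptor kinase AXL at -1.67 (SE 0.18). TGFB2 had a FaDu mean of 0.531 CPM, so its fold rests on few counts. Of 14 m5C writers, readers and erasers 2 rose and 2 fell, NSUN2 included (3 and 2 adjusted over the list alone; camera adjusted p = 0.231). The m5C reader ALYREF rose from 82.4 ± 8.79 to 259 ± 87.8 CPM, and the dioxygenase TET3 by 1.40 (SE 0.12). The other methyltransferases NSUN3, NSUN4, NSUN5, NSUN6 and NOP2 were at log2 folds of 0.21, 0.28, 0.30, -0.32 and 0.55 and did not pass the test, and NSUN7 fell by 1.31 (SE 0.30) from a level of 1.36 CPM. The call of NSUN7 was lost without FaDu replicate 2 or 3 or shNSUN2 replicate 1 (adjusted p = 0.0709, 0.102 and 0.0606). With the replicate number as a block, NSUN7 and NF2 also lost their calls (edgeR adjusted p = 0.0604 and 0.0603). Of 19 m6A factors 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.256), the latter being the mRNA-binding IGF2BP2 at -1.31 (SE 0.12). None of this list rose without FaDu replicate 2 or 3, and 1 rose without shNSUN2 replicate 1.

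Several other lists had members going both ways without a call by camera in the main fit. Of 29 NF-kB and cytokine genes 5 rose and 8 fell (camera adjusted p = 0.8). The chemokines CXCL8 and CXCL1 rose by 1.47 and 1.70, while IL1B and PTGS2 fell by 1.82 and 2.03. Of 26 growth factor and ERK feedback genes 5 rose and 4 fell (camera adjusted p = 0.452), with DUSP5 at 2.19, CCND1 at 1.47 and AREG at -0.95. Of 23 metalloproteinase and protease regulator genes 5 rose and 6 fell (camera adjusted p = 0.542), with MMP10 at 2.49 and SERPINE2 at -1.45. Of 20 cytosolic aminoacyl-tRNA synthetases 4 rose and 5 fell (camera adjusted p = 0.542), with WARS1 at -1.38 and KARS1 at 0.81. Of 20 immediate early genes 1 rose and 4 fell (camera adjusted p = 0.361), with EGR1 at -1.60. Of 34 epithelial junction genes 7 rose and 5 fell (camera adjusted p = 0.054). Of 28 hypoxia genes 1 rose and 7 fell (camera adjusted p = 0.0761), and of 21 Wnt and Notch target genes 2 rose and 7 fell (camera adjusted p = 0.0754). Adjusted over the list alone, the genes higher and lower in these 8 lists numbered 7 and 8, 6 and 5, 6 and 6, 6 and 7, 1 and 4, 10 and 6, 1 and 7, and 2 and 7. Without FaDu replicate 1, 2 or 3 or shNSUN2 replicate 1 the hypoxia genes that fell numbered 2, 2, 3 and 3 and the Wnt and Notch targets 3, 2, 2 and 2. In the same order, 2, 2, 3 and 4 junction genes rose and 2 fell each time, 1 synthetase rose each time and 2, 2, 2 and 3 fell, and 4, 2, 2 and 4 NF-kB and cytokine genes rose and 4, 6, 5 and 5 fell. Of the growth factor and ERK feedback genes 3 rose each time and 2, 2, 1 and 3 fell, of the protease genes 3 rose each time, and 2, 3, 2 and 3 immediate early genes fell. Without shNSUN2 replicate 3, 12 junction genes rose. No hypoxia gene rose without FaDu replicate 1 or 3 or shNSUN2 replicate 1 or 2, no immediate early gene without any library but FaDu replicate 3, and 1 Wnt and Notch target without any library but shNSUN2 replicate 3. Some of these lists were called in other fits. Camera called hypoxia genes lower without shNSUN2 replicate 2 (adjusted p = 0.00774), Wnt and Notch targets lower without replicate 3 (adjusted p = 0.0352), and junction genes higher without FaDu replicate 1 or shNSUN2 replicate 3 (adjusted p = 0.0243 and 0.0263). In the main fit fry called junction genes and growth factor and ERK feedback genes higher (adjusted p = 0.0104 and 0.0122), and synthetases and Wnt and Notch targets lower (adjusted p = 0.0104 and 0.0149). TGF-beta targets, p53 targets, NRF2 targets, apoptosis regulators, glycolysis enzymes, endoplasmic reticulum chaperones and replication-dependent histones had camera adjusted p = 0.268, 0.562, 0.694, 0.105, 0.202, 0.904 and 0.221, and fry called the apoptosis regulators higher (adjusted p = 0.0104). Of the markers of cells that a mixed culture could hold, the leukocyte list was not run and camera called none of the others in the main fit, with adjusted p = 0.554 for 8 fibroblast markers, 0.528 for 5 endothelial markers and 0.138 for 5 markers of an embryonic kidney line, which fry called lower (adjusted p = 0.0125).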

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

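The alternatives that correct for GC content and length, leave out mitochondrial and ribosomal DNA-like transcripts, or divide counts by 4 were chosen after the data had been seen. NSUN2 was called under every alternative run, with log2 folds of -1.88 to -2.15. No result reversed. At an adjusted p under 0.01, 1089 genes were called, 395 higher and 694 lower, 800 of them at least 2-fold. Leaving out 1 library gave 1354 to 4271 called genes, 478 to 2090 higher, 861 to 2181 lower and 994 to 1765 changed at least 2-fold. The lowest counts came without a FaDu library (1596, 1356 and 1354) and without shNSUN2 replicate 1 (2069). The most calls came without shNSUN2 replicate 3 and the most changes of at least 2-fold without replicate 2. With the GC and length correction 4946 genes were called, 2729 higher and 2217 lower. Leaving out shNSUN2 replicate 2 or 3 gave 3520 and 4271 calls from as few libraries, and the cause of these shifts was not tested. Other scalings, filters and tools gave 3288 to 4267 calls, and scaling by totals moved the median of all genes by -0.05 on the log2 scale. With the replicate number as a block, 2370 genes were called, 969 of them higher. Deviations of libraries sharing a number correlated at -0.04, 0.02 and 0.01 across genes, so no pairing by number was seen. With 3 libraries per group this cannot show that the experiments were unpaired. With an estimated correlation 0 of 19 lists stayed called. Of 20 lists called by fry, 13 were among the 19. Across filters, tools and the block all 19 were kept. Lists not called in the main fit were gained by camera with no filter (hypoxia genes at adjusted p = 0.0372, epithelial junction genes at 0.0252, Wnt and Notch target genes at 0.0314), with the DESeq2 Wald test (hypoxia genes at 0.0464, endothelial markers at 0.0162), with the GC and length correction and with ranks (epithelial junction genes at 0.0447 and 0.0402), and with counts divided by 4 (replication-dependent histones at 0.0389). Leaving out mitochondrial transcripts removed their list by construction, and dividing counts by 4 lost heat shock genes (adjusted p = 0.0596). Single named genes lost their call in 184 of the comparisons and gained one in 14. With 1 fragment often worth 4 units, depth limits what can be said of genes under about 1 CPM.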

Other observations

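The gene families of the next 2 paragraphs, and the tests of prostate markers, of androgen response genes and of the spread among mitochondrial transcripts, were chosen only after the result had been seen, as was the GC and length correction.

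Subunits of protein-folding and protein-degrading machines were higher in shNSUN2. Of 37 proteasome subunits 22 rose and none fell, with a median log2 fold of 0.51 (22 was 7, 6 and 4 without FaDu replicate 1, 2 or 3, and 11 without shNSUN2 replicate 1). PSMB5, which carries the chymotrypsin-like activity, rose from 96.9 ± 14.7 to 214 ± 40.8 CPM. Of 9 genes of the chaperonin CCT, which folds actin and tubulin, 6 rose and 1 fell (5, 4 and 3 rose without FaDu replicate 1, 2 or 3), with CCT7 going from 486 ± 28.9 to 902 ± 183 CPM. The 6 subunits of the MCM helicase, part of which are in the G1/S list, all rose, with a median log2 fold of 1.12, and stayed called without any 1 library. The 5 families of these 2 paragraphs were picked because their genes had moved, so a test of them as sets is not evidence. With an estimated correlation all 5 had a camera adjusted p = 0.0969. The fifth is HLA class II, of which HLA-DPA1 and HLA-DRB1 rose from 0 in FaDu to 0.27 and 0.283 CPM while HLA-DPB1 did not pass the test. Neither was called when a FaDu library or shNSUN2 replicate 1 was left out.

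The keratins of simple epithelia rose, while the basal keratins KRT14, KRT5 and KRT17 fell and KRT15 rose. KRT8 went from 265 ± 45.2 to 1340 ± 167 CPM and its partner KRT18 from 195 ± 22.3 to 643 ± 108 CPM (edgeR adjusted p = 0.000343 and 0.000719). KRT7 rose by 2.46 (SE 0.21) and KRT19 by 0.60 (SE 0.12) on the log2 scale. Of the 4 genes 3 were still called without FaDu replicate 1, 2 or 3. Also picked after they were seen were 4 noncoding RNAs that fell, with RMRP at -3.63 (SE 0.64), RPPH1 at -2.81 (SE 0.48) and the signal recognition particle RNAs RN7SL1 and RN7SL2 at -0.84 and -0.89. RMRP had 8.47, 2.38 and 2.24 CPM in the FaDu libraries, so its level also varied within that group, and its log2 fold was -2.72 without FaDu replicate 1. RPPH1 likewise had 7.18, 3.10 and 2.46 CPM there, and its log2 fold was -2.20 without FaDu replicate 1. These 4 RNAs have no poly(A) tail. RN7SK, which also lacks one, was at -4.00 (SE 0.63), with 41.1, 14.2 and 9.17 CPM in the FaDu libraries. Of 21 replication-dependent histone genes, whose mRNAs lack a tail too, 3 rose and none fell (camera adjusted p = 0.221). The 3 were 1, 1 and 0 without FaDu replicate 1, 2 or 3, and 0 without shNSUN2 replicate 1. These values do not decide whether RNAs without a tail fell as a class, and a difference in RNA selection was not tested.

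The real grouping gave 3532 called genes, and the highest of the other 9 splits of the 6 libraries gave 3. Each of those 9 splits mixes both groups, so the group difference widens the spread within each part and lowers the calls. Their low counts are therefore not a reference for a comparison without a group difference. As 1 of 10 splits reached the real count, the splits are too few for a share under 0.05.

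The first pattern is the rise of KLK2, KLK3, KLK4 and TMPRSS2 in shNSUN2, where KLK4 was at 0 in every FaDu library and at 0.399 to 0.892 CPM in shNSUN2. A wider androgen response was not decided, with 7 genes higher and 6 lower in a list of 53 other androgen response genes and a camera p of 0.434. Of 22 other prostate markers 31.8% rose, OR51E2, TMEFF2 and MSMB among them, while 3 fell, STEAP1 and SLC30A4 among them, from levels that would hide a small admixture. RNA of prostate tissue is left open. Of 20 smooth muscle and plasma cell genes low in FaDu, listed before their values were seen, 45% were over 2 times higher in shNSUN2. This was short of the 50% set in advance, against 8.29% of protein-coding genes low in FaDu. Most of the genes that were higher were related immunoglobulin genes, such as IGHG1, IGHG2 and IGLC2, which are not separate pieces of evidence. IGKC, of the same family, was picked after its values were seen, so the share may not be an independent check. Without shNSUN2 replicate 1 the share was 20%, and 45% to 55% without any other library, so it rests on that replicate. IGHG1 had 1.45, 0.522 and 0.222 CPM in shNSUN2. DES and MSMB were also highest in shNSUN2 replicate 1, with DES at 2.75, 0.455 and 0.459 CPM. KLK3 was not, at 14, 16.8 and 10.2 CPM. These unequal proportions go against 1 source in a fixed proportion, but they rest on replicate 1 and on low counts. Whether there was 1 source, several sources or expression in FaDu cells cannot be told apart.

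The second pattern is the fall of the mitochondrial mRNAs. The gap of 2.66 (SE 0.20) on the log2 scale between MT-RNR1 and MT-ND4 argues against an equal loss of all mitochondrial RNA. A GC or length trend is argued against by a median of -0.74 after the correction. Without shNSUN2 replicate 3, the library that stood apart by this trend, the median was -0.79. The median was -0.76 at its highest under totals or DESeq2 size factors, but these moved the median of all genes by only -0.054 and 0.005, too little to have changed it. A scaling moves every gene of a library alike. It cannot part the list, at a median of -0.768, from all tested genes, at -0.007, nor MT-RNR1 from MT-ND4. These values argue against scaling as the cause of the fall relative to other genes. A difference in mitochondrial transcription or RNA decay after NSUN2 loss may remain as an explanation and was not tested, nor was a difference in RNA selection during library preparation.

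The third pattern is the rise of the G1/S, mitochondrial ribosomal and cytosolic ribosomal lists beside the GC and length trend of shNSUN2 replicate 3. After the correction their medians were 0.79, 0.42 and 0.17, against 0.74, 0.38 and 0.18 before, and each stayed past camera's threshold. Without that library the G1/S and mitochondrial ribosomal medians were 0.79 and 0.26, with both still called. For these lists the values argue against the trend as the whole cause. The cytosolic ribosomal median was 0.03 without that library, with the call lost, so this last list rests on replicate 3. The correction hardly moved the cytosolic list, did not remove what replicate 3 adds to it and cannot decide whether the trend lies behind it. Faster cycling of the knockdown cells may lie behind the G1/S list and was not tested, since growth was not measured here and culture density at harvest is not given in the sources used here.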
